A study of Mus musculus with 12 samples.

How the data were processed

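RNA was taken from kidneys of adult wild-type mice and mice with a deletion of Ybx3, without injury or after experimental ischemia/reperfusion injury, with 3 samples in each of 4 groups. Per the labels' protocols, ribosomal RNA was depleted from total RNA with a Ribo-off kit, strand-marking libraries were made with the NEBNext Ultra II Directional kit, and both ends of the fragments were sequenced on a NovaSeq instrument. Per the submitters' processing notes, STAR and the mouse build mm10 were used. The version of STAR, the counting tool, whether counting used the strand, the time after injury and the sex of the mice are not given in the sources used here. The authors deposited a table of whole-number read counts per Ensembl gene, with 1 column for each of the 12 samples and no normalization. Column names were matched to the sample titles, and every sample column was used.

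The table held 42748 genes, of which 42548 were found in GENCODE M21 by their identifier. Coordinates are those of mm10. In all, 15562 genes were at 0 in every library. Among 1260 protein-coding genes whose whole span lies within the spans of other genes, 84.6% were at 0, against 9.29% of 20145 with some span of their own. The 37 genes of the mitochondrial genome and Xist were at 0 in every library, so that no statement on them was possible. Total counts per library are given with the results. The small RNAs Rn7s1 and Rn7s2 took 9.892% to 13.62% of the counts. Libraries of the same group differed by more than sampling noise, and no library was counted as a copy of another. Slc7a5 was not among the genes tested.

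Differences were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group, a minimum count of 10 and a minimum total of 15, which left 19218. Library sizes were scaled by TMM (factors 0.9002 to 1.06), and all 12 libraries entered 1 quasi-likelihood fit with a coefficient per group. The 5 comparisons were IRI in each genotype, knockout against wild type in each condition, and the interaction of genotype and IRI. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05 over all genes tested. CPM are counts relative to the TMM-scaled library size, as edgeR gives them, and log2 fold changes are given with the standard error of the fit.

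Gene lists, 44 in number, covered kidney cell types, injury and stress responses, mitochondrial functions, and tissues or cells that a kidney sample could carry along. The 42 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists within each comparison, and again with the correlation estimated for each list. With the estimated correlation no list passed in any of the 5 comparisons. Fry of limma was run as a further test. As a directional test it called 22 lists for IRI in wild type, 16 for IRI in knockout and 0 in the other comparisons. Members were also counted when adjusted over the list alone. A list's camera test compares its members with the other genes and does not say that each member changed.

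The lists, the tests, the comparisons and the rule for named genes were set before the data were examined. In each comparison the rule took up to 6 genes per direction with the largest log2 fold change among called protein-coding genes of at least 1 CPM in the higher group whose replicates did not overlap. It took up to 2 called members per direction of each list. It took Ybx3, Ybx1, Ybx2, Havcr1, Lcn2, Slc7a5, Slc3a2, Ppargc1a, Krt18 and Umod whatever their values. It also took up to 10 genes called in both genotype comparisons, up to 10 called genes within 20 Mb of Ybx3, and, where fewer than 5 genes passed, the 5 with the smallest p. Some genes that the rule took are not reported here. Other genes in the text are the Y-linked and adrenal genes, chosen after their values were seen.

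Called genes near Ybx3 were compared with the rest by Fisher's exact test, two-sided. Alternatives set in advance were RLE scaling, library sizes alone, scaling without mitochondrial and ribosomal RNA genes, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 samples, a fit of only the groups compared, a replicate block, a fold threshold, and leaving out each library. Alternatives added after seeing the data were a Y-linked covariate, fits without the adrenal libraries or without the libraries of intermediate Y-linked level, a fit without small RNA and pseudogenes, and the mean of the genotype comparisons.

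The procedure was tested on simulated data with 200 of 19218 genes changed. Of 100 genes changed 4-fold, 82% were recovered in the comparison of control kidneys and 76% after IRI, and of 100 changed 2-fold 35% and 34%, with 5 and 8 false calls. For the interaction the shares were 61% and 51% at 4-fold and 7% and 8% at 2-fold, with 4 and 1 false calls. Camera called 0 of 40 unchanged sets in each simulation. The simulated genes were drawn independently of each other, so that this does not test the preset correlation. In the real data the estimated correlation was higher, such as 0.816 for the cytosolic ribosome for IRI in wild type. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.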

Results

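Total RNA of the kidney was sequenced from adult mice of 2 genotypes, wild type and a deletion of Ybx3, in 2 conditions, uninjured control and after renal ischemia/reperfusion injury (IRI), in which blood flow to the kidney is stopped and then restored. Ybx3 encodes DNA-binding protein A, a cold shock domain protein that binds DNA and RNA. Each of the 4 groups held 3 libraries, 12 in all. The labels name separate samples and give no more on their origin, so that p-values measure only the spread between these samples. The deposited counts totalled 50353621, 58787224 and 49715880 in wild-type control replicates 1 to 3 and 50190848, 52583283 and 52220355 in wild-type IRI. They totalled 61563411, 67948710 and 67326646 in knockout control and 62350202, 64372902 and 39074224 in knockout IRI, and 22567 to 23580 genes per library had at least 1 count. The design asks what IRI changed in each genotype, what the deletion changed in each condition, and whether the response to IRI differed between genotypes. The series title names a role of the protein in the injury and in mitochondria. Of 42748 genes, 19218 passed the filter on low counts and were tested.

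Ybx3 (ENSMUSG00000030189, chromosome 6, 131364855 to 131388476, mm10) was lower in every knockout library than in every wild-type library. It reached 33.4 ± 3.35 CPM in wild-type control kidneys and 10.6 ± 2.03 CPM in knockout control kidneys (mean ± SD, n = 3 each). After IRI it reached 79.8 ± 25.3 CPM in wild type and 15.9 ± 2.49 CPM in knockout (n = 3 each). Between 599 and 1050 counts remained in each knockout library, and the deleted part of the gene is not given in the sources used here. In wild-type kidneys Ybx3 rose after IRI, with a log2 fold change of 1.26 (SE 0.23, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.00568). After IRI it was lower in knockout than in wild type by a log2 fold change of -2.33 (SE 0.23, edgeR adjusted p = 0.00719). In control kidneys the log2 fold change was -1.66 (SE 0.23), which did not pass the threshold over all genes tested (edgeR adjusted p = 0.0784). The call after IRI ended without knockout IRI replicate 1 (edgeR adjusted p = 0.0973) or replicate 2 (edgeR adjusted p = 0.0934), with the replicate block (edgeR adjusted p = 0.0568) and with only the 2 groups compared (edgeR adjusted p = 0.711). The control difference passed without knockout control replicate 1 (edgeR adjusted p = 0.0141), wild-type IRI replicate 2 (edgeR adjusted p = 0.0106) or wild-type IRI replicate 3 (edgeR adjusted p = 0.0329). Of the other cold shock domain genes, Ybx2 fell after IRI in wild type (log2 fold change -1.52, edgeR adjusted p = 0.0199), and Ybx1 had a log2 fold change of 0.54 (edgeR adjusted p = 0.0971). Carhsp1 was called higher, so that the list had 2 higher, Ybx3 included, and 1 lower of 7 (camera adjusted p = 0.457). The Ybx2 call ended without wild-type control replicates 2 or 3 or wild-type IRI replicate 1 (edgeR adjusted p from 0.0628 to 0.0728), with only the 2 groups compared (edgeR adjusted p = 0.0654) and with the Y-linked level as a covariate, a setting chosen after seeing the data (edgeR adjusted p = 0.0979). Ybx1 passed without wild-type IRI replicate 2 (edgeR adjusted p = 0.0429) or knockout control replicate 1 (edgeR adjusted p = 0.0368).

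**Figure D1:**
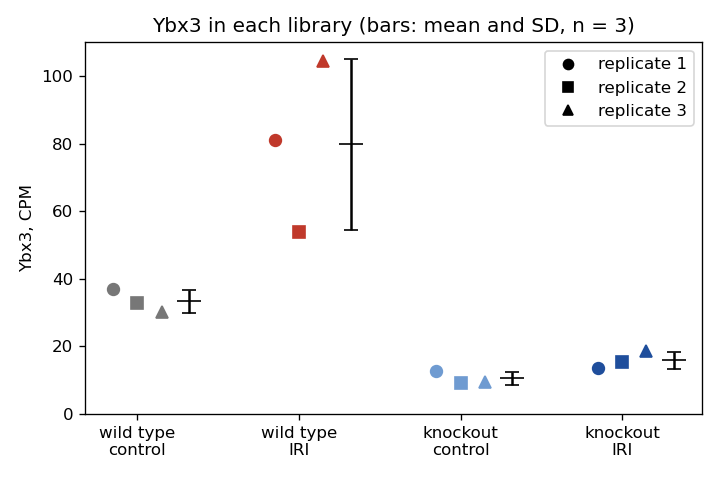
Ybx3 in CPM (counts scaled to library size, vertical axis) in each of the 12 libraries, by group (horizontal axis); marker shapes give the replicate number, and bars the mean and SD of 3 libraries. The knockout libraries lie between 9.28 and 18.6 CPM and the wild-type libraries between 30.2 and 104 CPM.

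Transcripts of the Y chromosome differed between libraries of the same group. The summed level of Ddx3y, Kdm5d, Eif2s3y and Uty was 1.14, 1.79 and 1.54 CPM in wild-type control replicates 1 to 3. It was 206.6, 33.2 and 307.1 CPM in wild-type IRI, 1.18, 248.5 and 261.2 CPM in knockout control, and 45.2, 227.4 and 1.26 CPM in knockout IRI. The labels give no sex, and Xist, the RNA of the inactive X chromosome, was at 0 counts in every library. Genes of the adrenal gland, the hormone gland above the kidney, were high in a pair of libraries. The summed level of Star, Cyp11a1, Cyp11b1, Cyp21a1 and Hsd3b1, all of steroid hormone synthesis, was 271.7 CPM in knockout IRI replicate 1 and 1397 CPM in replicate 2. It lay between 5.15 and 7.49 CPM in the other 10 libraries, where most of it was Star. The wild-type IRI libraries were spread on the first principal component of all tested genes, which held 48.9% of the variance. Replicates 1 to 3 lay at 67.0, 13.3 and 111.8. On the second component, with 15.2% of the variance, replicate 3 lay apart, at 58.6 against -12.2 and -19.7 for replicates 1 and 2.

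**Figure D2:**
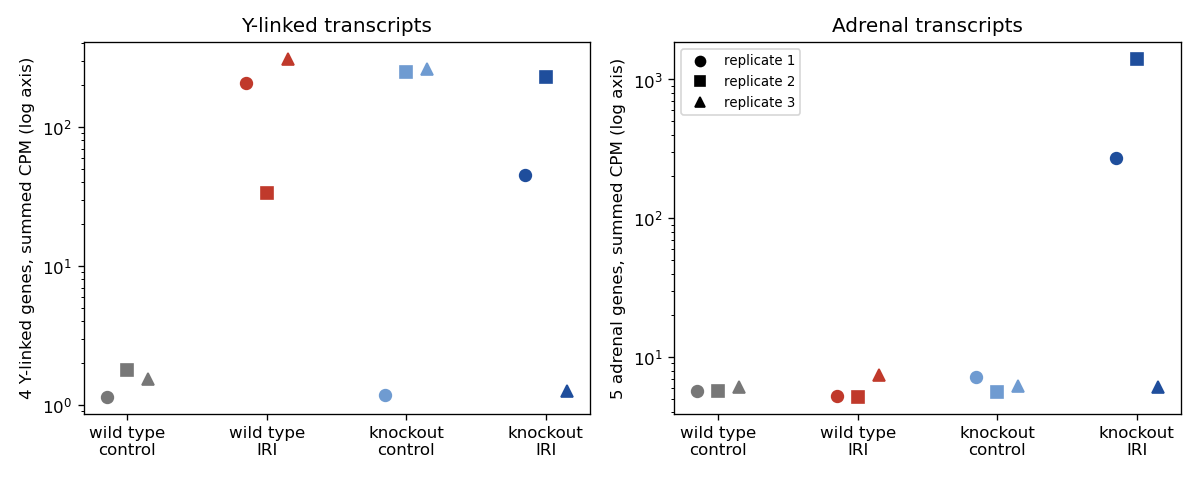
Summed CPM (vertical log axes) of 4 Y-linked genes (left) and of 5 adrenal steroid synthesis genes (right) in each library, by group; marker shapes give the replicate number. The 3 wild-type control libraries lie under 1.8 CPM of Y-linked transcripts, and adrenal transcripts reach 271.7 and 1397 CPM in knockout IRI replicates 1 and 2.

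In wild-type kidneys IRI raised genes of the injured tubule and lowered genes of the transport and energy functions of the nephron. Havcr1, which encodes the kidney injury marker KIM-1, went from 1.34 ± 0.19 to 616 ± 224 CPM (SD, n = 3), a log2 fold change of 8.84 (SE 0.49, edgeR adjusted p = 3.1e-05). Lcn2, the injury marker neutrophil gelatinase-associated lipocalin, rose by a log2 fold change of 7.70 (SE 0.63, edgeR adjusted p = 0.000356), and the keratin gene Krt20 by 9.25 (SE 0.93, edgeR adjusted p = 0.000638). Of the 30 tested genes on the tubular injury and repair list, 27 rose and none fell, or 28 and none when adjusted over the list alone (median log2 fold change 2.09, camera adjusted p = 8.41e-39, and adjusted p = 0.16 with an estimated correlation). In all, 4320 genes passed the threshold, 2512 higher and 1808 lower, which is 22.5% of the genes tested, and 1928 of them changed at least 2-fold.

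Genes of the nephron segments were mostly lower. Of 31 proximal tubule genes, 14 fell and 1 rose, or 19 and 5 when adjusted over the list alone (median log2 fold change -1.05, camera adjusted p = 1.1e-06, and adjusted p = 0.41 with an estimated correlation). They included Gatm of creatine synthesis (log2 fold change -2.66) and Miox of inositol breakdown (-2.23). The gene that rose, Acsm3 (4.60), is also on the list of male-biased kidney genes. Of 17 genes of the thick ascending limb and distal tubule, 9 fell and none rose, or 14 when adjusted over the list alone (median -1.28, camera adjusted p = 5.78e-10, and adjusted p = 0.41 with an estimated correlation). Egf, of the distal nephron, went from 2080 ± 81.3 to 268 ± 168 CPM (SD, n = 3), and Pvalb, which skeletal muscle also expresses, had a log2 fold change of -3.85. Myh1, a myosin heavy chain gene of skeletal muscle, was at 1.15 ± 0.20 CPM (SD, n = 3) in control libraries and at 0 in all 3 IRI libraries (edgeR adjusted p = 0.0343). Umod, which encodes uromodulin of the thick ascending limb, had a log2 fold change of -0.36 (SE 0.23) and did not pass (edgeR adjusted p = 0.278). Of 16 collecting duct genes, 9 fell and none rose, or 13 when adjusted over the list alone (median -0.88, camera adjusted p = 5.65e-07, and adjusted p = 0.41 with an estimated correlation). The water channel gene Aqp4 (-2.58) and the anion exchanger gene Slc26a4 (-1.41) were among them. The call of Myh1 ended without any 1 of the wild-type control libraries, wild-type IRI replicates 1 or 3 or knockout IRI replicate 1 (edgeR adjusted p from 0.0505 to 0.0824). That of Acsm3 ended without any 1 of the wild-type control libraries or wild-type IRI replicates 1 or 3 (edgeR adjusted p from 0.0662 to 0.105), and that of Gatm without wild-type IRI replicate 1 (edgeR adjusted p = 0.0517). Umod passed without wild-type IRI replicate 2 (-0.70, edgeR adjusted p = 0.0117). The calls of Acsm3 (1.29), Gatm, Miox, Egf and Slc26a4 ended with the Y-linked covariate (edgeR adjusted p from 0.0653 to 0.158). That of Gatm ended with only the 2 groups compared (edgeR adjusted p = 0.0609). That of Acsm3 ended with the replicate block (edgeR adjusted p = 0.0503) and limma-voom (limma-voom adjusted p = 0.203). Without the adrenal libraries (knockout IRI replicates 1 and 2) or those of intermediate Y-linked level (wild-type IRI replicate 2 and knockout IRI replicate 1), both chosen after seeing the data, the Myh1 call ended (edgeR adjusted p = 0.0563 and 0.0589).

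Most neutrophil and cytokine genes rose while most lymphocyte genes fell. Of 12 neutrophil genes, 10 rose and none fell, and the same number when adjusted over the list alone (median log2 fold change 5.29, camera adjusted p = 7.36e-10, and adjusted p = 0.41 with an estimated correlation). S100a8, a calcium-binding protein of neutrophils, went from 0.017 ± 0.029 to 3.26 ± 2.21 CPM. Of 29 cytokine and NF-kB response genes, 19 rose and none fell, or 22 when adjusted over the list alone (median 1.68, camera adjusted p = 5.16e-13, and adjusted p = 0.33 with an estimated correlation). The neutrophil-attracting chemokine genes Cxcl2 (8.62) and Cxcl1 (7.28) changed most by log2 fold change. Of 15 lymphocyte and NK cell genes, 9 fell and none rose, or 11 when adjusted over the list alone (median -1.34, camera adjusted p = 2.28e-05, and adjusted p = 0.33 with an estimated correlation), among them Jchain (-2.50) and the T cell receptor subunit gene Cd3g (-2.46). Of 19 complement and antigen presentation genes, 8 fell and 1 rose, or 9 and 2 when adjusted over the list alone (median -0.47, camera adjusted p = 0.00176, and adjusted p = 0.41 with an estimated correlation). The MHC class II genes H2-Eb1 (-1.29) and H2-Aa (-1.21) fell, and the complement receptor gene C5ar1 (1.92) rose. Interferon response genes had none higher and 1 lower of 30 (camera adjusted p = 0.774). Macrophage and monocyte genes went both ways, with 6 higher and 1 lower of 23, or 7 and 3 when adjusted over the list alone (camera adjusted p = 0.132): Cd14, a receptor for bacterial lipopolysaccharide, rose (4.37) and Csf1r, the receptor for macrophage growth factor, fell (-1.02). The calls of Cxcl2 and Jchain ended with the Y-linked covariate (edgeR adjusted p = 0.0791 and 0.0595), and that of Jchain with only the 2 groups compared (edgeR adjusted p = 0.0633).

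Nuclear genes of the mitochondrial energy machinery were lower by less than 2-fold at the median. Of 35 complex I genes, 20 fell and none rose, or 27 when adjusted over the list alone (median log2 fold change -0.47, camera adjusted p = 6.3e-09, and adjusted p = 0.43 with an estimated correlation), with Ndufc1 at -0.80 and Ndufs8 at -0.77. Of 16 ATP synthase genes, 11 fell and none rose, or 15 when adjusted over the list alone (median -0.49, camera adjusted p = 4.5e-06, and adjusted p = 0.43 with an estimated correlation). Of 22 TCA cycle genes, 11 fell and none rose, or 13 when adjusted over the list alone (median -0.38, camera adjusted p = 1.11e-05, and adjusted p = 0.46 with an estimated correlation), among them Idh2 (-1.08) and Mdh1 (-0.90). Complexes II and III had 8 lower of 16, or 11 when adjusted over the list alone, Sdhb among them at -0.78 (camera adjusted p = 0.000262, and adjusted p = 0.46 with an estimated correlation). Complex IV had 8 lower of 16, or 12 when adjusted over the list alone, with Cox7a1, an isoform of heart and skeletal muscle, at -1.39 (camera adjusted p = 0.000352, and adjusted p = 0.41 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial gene expression, fell (-1.21, SE 0.28, edgeR adjusted p = 0.0142), and the related Pprc1 rose (1.28). The 24 mitochondrial biogenesis genes had 1 higher and 3 lower (camera adjusted p = 0.509), and the 31 genes of the mitochondrial ribosome 1 higher and none lower (camera adjusted p = 0.902). The 13 protein genes of the mitochondrial genome were at 0 counts in every library and were not tested. Fatty acid oxidation and peroxisome genes went both ways, with 12 higher and 5 lower of 31, or 14 and 8 when adjusted over the list alone (camera adjusted p = 0.0487, and adjusted p = 0.61 with an estimated correlation). That list no longer passed without wild-type control replicates 2 or 3 or knockout IRI replicate 2 (camera adjusted p = 0.0873, 0.19 and 0.0794). Pdk4, a kinase that holds back glucose oxidation, rose (5.54, or 2.54 without wild-type IRI replicate 3), and Acadm, an acyl-CoA dehydrogenase, fell (edgeR adjusted p = 0.0175). The Pdk4 call ended without wild-type control replicates 2 or 3 (edgeR adjusted p = 0.0591 and 0.0599). That of Acadm ended without wild-type control replicate 1 or wild-type IRI replicate 1 (edgeR adjusted p = 0.0543 and 0.0621). That of Ppargc1a ended without wild-type control replicate 3 or wild-type IRI replicate 1 (edgeR adjusted p = 0.0569 and 0.0532). With only the 2 groups compared the calls of Ndufs8, Ppargc1a, Pdk4 and Acadm ended (edgeR adjusted p from 0.0505 to 0.0681). Those of Ndufs8, Pprc1, Pdk4 and Acadm ended with the Y-linked covariate (edgeR adjusted p from 0.0501 to 0.138). Ppargc1a was at -0.78 with it.

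More genes rose than fell among immediate early genes and genes of cell cycle arrest, antioxidant defence and the cytosolic ribosome. The 19 hypoxia response genes had 2 higher and 3 lower (camera adjusted p = 0.986). Of 19 immediate early genes, 12 rose and none fell, or 13 when adjusted over the list alone (median log2 fold change 1.68, camera adjusted p = 1.82e-07, and adjusted p = 0.41 with an estimated correlation), with Fosl1 at 4.03. Without wild-type IRI replicate 3 that median was 0.96. Of 19 genes of the p53 and cell cycle arrest list, 9 rose and none fell, or 12 when adjusted over the list alone (median 1.04, camera adjusted p = 1.51e-05, and adjusted p = 0.41 with an estimated correlation), with the cell cycle inhibitor gene Cdkn1a at 4.10 (2.67 without wild-type IRI replicate 3) and Gdf15 at 3.96. Of 30 antioxidant genes, 13 rose and 2 fell, or 15 and 3 when adjusted over the list alone (camera adjusted p = 0.000412, and adjusted p = 0.41 with an estimated correlation). Heme oxygenase 1, Hmox1 (4.29), and the metallothionein gene Mt2 (3.94) rose, and the mitochondrial superoxide dismutase gene Sod2 fell (edgeR adjusted p = 0.032). The Sod2 call ended without any 1 of the wild-type control libraries or wild-type IRI replicate 1 (edgeR adjusted p from 0.0678 to 0.0943), with only the 2 groups compared (edgeR adjusted p = 0.0885) and without the intermediate libraries (edgeR adjusted p = 0.0508). The calls of Cdkn1a, Mt2 and Sod2 ended with the Y-linked covariate (edgeR adjusted p from 0.0533 to 0.104). Fosl1 was at 2.55 with it. Of 29 genes of the cytosolic ribosome, 14 rose and none fell, or 22 when adjusted over the list alone (median 0.32, camera adjusted p = 4.76e-06, and adjusted p = 0.53 with an estimated correlation). Of 26 fibroblast and extracellular matrix genes, 10 rose and 2 fell, or 12 and 5 when adjusted over the list alone (median 0.43, camera adjusted p = 0.00774, and adjusted p = 0.43 with an estimated correlation). This call ended without wild-type IRI replicate 2 (median 0.058, camera adjusted p = 0.195) and without both intermediate libraries, a setting chosen after seeing the data (0.052, camera adjusted p = 0.171), and the median was 0.74 without wild-type IRI replicate 3. Tenascin C, Tnc (2.51), rose, and Lum (-2.03) fell. Cell death genes (12 higher, 2 lower of 31) and heat shock and unfolded protein genes (10 higher, none lower of 28) also rose more than they fell. When adjusted over each list alone the counts were 12 and 2 for cell death and 12 and none for heat shock (camera adjusted p = 0.00176 and 0.00434, and adjusted p = 0.41 for both with an estimated correlation). The median of the cell death genes was 0.24, and 0.43, 0.36 and 0.13 without wild-type IRI replicates 1, 2 and 3. That of the heat shock genes was 0.30, and 0.14 without wild-type IRI replicate 2.

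Some genes known to differ between male and female kidneys also passed. Eif2s3y (8.30) and Ddx3y (7.88) passed, as did 4 higher and none lower of 10 male-biased kidney genes, or 7 and 1 when adjusted over the list alone (median log2 fold change 3.88, camera adjusted p = 0.0213, and adjusted p = 0.53 with an estimated correlation). Slco1a1, an organic anion transporter gene, was one of them (4.60). Of 7 female-biased genes 1 fell, Slc22a19 (-2.35), over all genes and when adjusted over the list alone (median -1.93, camera adjusted p = 0.0102, and adjusted p = 0.49 with an estimated correlation). With the Y-linked level as a covariate, a setting chosen after seeing the data, 1050 genes passed, 1005 of them among the 4320, and the calls of the male-biased and female-biased lists ended (camera adjusted p = 0.59 and 0.857). Without wild-type IRI replicate 2 the male-biased call also ended (camera adjusted p = 0.0719) and the female-biased median was -3.24. The calls of Eif2s3y, Ddx3y and Slco1a1 ended without any 1 of the wild-type control libraries or wild-type IRI replicates 1 or 3 (edgeR adjusted p from 0.0513 to 0.124). That of Slco1a1 also ended without knockout control replicates 2 or 3 or knockout IRI replicate 1 (edgeR adjusted p from 0.0539 to 0.0567). All 3 calls ended with the covariate (log2 fold changes of 4.60, 3.93 and 1.08, edgeR adjusted p from 0.0751 to 0.295) and in limma-voom (limma-voom adjusted p from 0.186 to 0.279), and those of Eif2s3y and Slco1a1 with the replicate block (edgeR adjusted p = 0.0549 and 0.0669). Without wild-type IRI replicate 2 the count was 7129, and without wild-type IRI replicate 1 or wild-type control replicates 1, 2 or 3 it was 2072, 2364, 1570 or 1694. With only these 6 libraries in the fit, 1232 genes passed.

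In knockout kidneys IRI also raised injury and cytokine genes and lowered proximal tubule genes. Havcr1 went from 1.17 ± 0.36 to 301 ± 142 CPM (SD, n = 3), a 256-fold rise (SE of the log2 fold change 0.48, edgeR adjusted p = 6.3e-05). Krt20 rose by a log2 fold change of 8.95 (edgeR adjusted p = 0.00167) and Lcn2 by 6.54 (edgeR adjusted p = 0.00077). In all, 1215 genes passed, 749 higher and 466 lower, which is 6.32% of the genes tested, and 678 of them changed at least 2-fold. With library sizes alone in place of TMM normalization the split was 1152 higher and 379 lower, so that the share of higher genes moved from 61.6% to 75.2%.

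Of the 30 tubular injury genes, 21 rose and none fell in knockout, or 24 when adjusted over the list alone (median log2 fold change 1.39, camera adjusted p = 1.77e-46, and adjusted p = 0.10 with an estimated correlation). Of 31 proximal tubule genes, 11 fell and none rose, or 22 when adjusted over the list alone (median -1.09, camera adjusted p = 9.22e-16, and adjusted p = 0.16 with an estimated correlation), among them Ass1 of arginine synthesis (-1.92) and Acsm2 (-1.91). The epithelial keratin gene Krt18 rose by 1.31 in knockout and 1.35 in wild type, and Umod had 0.25 in knockout and did not pass (edgeR adjusted p = 0.58). The glucose transporter family gene Slc5a4a (-3.69) and the complement gene C8b (-3.64) were among the genes that fell most. Of 17 genes of the thick ascending limb and distal tubule, 2 fell, Calb1 (-1.11) and Ptger3, or 4 when adjusted over the list alone (median -0.57, camera adjusted p = 0.000312, and adjusted p = 0.43 with an estimated correlation). Of 26 fibroblast and extracellular matrix genes, 11 rose and none fell, or 15 when adjusted over the list alone (median 0.83, camera adjusted p = 2.04e-10, and adjusted p = 0.16 with an estimated correlation), with Tnc at 2.14. The calls of Tnc and Krt18 in knockout ended without knockout control replicates 2 or 3 or knockout IRI replicates 2 or 3 (edgeR adjusted p from 0.0583 to 0.132). That of Acsm2 ended without any 1 of the wild-type control or knockout IRI libraries or knockout control replicates 2 or 3 (edgeR adjusted p from 0.059 to 0.141). That of Calb1 ended without any 1 of the control libraries or knockout IRI replicates 1 or 2 (edgeR adjusted p from 0.0691 to 0.161). That of Ptger3 ended without any 1 of the knockout libraries or wild-type control replicate 2 (edgeR adjusted p from 0.0543 to 0.138). Without the adrenal libraries, which leaves 1 knockout IRI library, the calls of Slc5a4a, C8b, Ass1, Acsm2, Calb1 (-0.65), Ptger3, Tnc and Krt18 all ended (edgeR adjusted p from 0.10 to 0.499). With the replicate block those of Acsm2, Calb1, Ptger3 and Krt18 ended (edgeR adjusted p from 0.0576 to 0.0978). Those of Acsm2, Calb1 and Krt18 ended with only the 2 groups compared (edgeR adjusted p from 0.0534 to 0.0689). Those of Calb1 and Ptger3 ended without TMM and without the intermediate libraries (edgeR adjusted p from 0.0517 to 0.0689), that of Acsm2 in limma-voom (limma-voom adjusted p = 0.0515), and that of Krt18 in wild type with the Y-linked covariate (edgeR adjusted p = 0.066).

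Of 29 cytokine genes, 12 rose and none fell in knockout, or 17 when adjusted over the list alone (median log2 fold change 1.44, camera adjusted p = 3.15e-14, and adjusted p = 0.16 with an estimated correlation), Cxcl1 among them (5.74). Of 12 neutrophil genes, S100a9 (4.68) and S100a8 (4.48) rose, and 8 did when adjusted over the list alone (median 2.59, camera adjusted p = 3.7e-06, and adjusted p = 0.37 with an estimated correlation). Macrophage and monocyte genes had 4 higher and 1 lower of 23, or 9 and 1 when adjusted over the list alone, with the lysosomal marker gene Cd68 at 1.96 and Csf1r at -1.06 (camera adjusted p = 0.00184, and adjusted p = 0.37 with an estimated correlation). Of 30 interferon response genes, 4 rose and none fell, Oasl2 (0.79) among them, and the same number when adjusted over the list alone (camera adjusted p = 0.000406, and adjusted p = 0.49 with an estimated correlation). Of 15 lymphocyte genes, 3 fell, Cd3d (-2.44) among them, or 8 when adjusted over the list alone (median -1.20, camera adjusted p = 1.05e-06, and adjusted p = 0.16 with an estimated correlation). Complement component C3 rose by a log2 fold change of 2.42 (edgeR adjusted p = 0.02). Its list of 19 complement and antigen presentation genes had 2 higher and 4 lower, H2-Aa and H2-Eb1 among the lower. When adjusted over the list alone 5 were higher and 5 lower (camera adjusted p = 0.472). The calls of Cxcl1 and S100a8 ended without knockout control replicates 2 or 3 (edgeR adjusted p from 0.0525 to 0.066). That of Cd3d ended without knockout control replicate 2 or knockout IRI replicate 2 (edgeR adjusted p = 0.0569 and 0.0673). That of C3 ended without knockout control replicates 2 or 3 or knockout IRI replicates 2 or 3 (edgeR adjusted p from 0.0661 to 0.0915). That of Oasl2 ended without knockout control replicate 3 or knockout IRI replicates 2 or 3 (edgeR adjusted p from 0.0848 to 0.099). Without the adrenal libraries the calls of Cxcl1, S100a9, S100a8, Cd3d, Oasl2 and C3 ended (edgeR adjusted p from 0.0734 to 0.212). That of Cxcl1 ended in limma-voom (limma-voom adjusted p = 0.0532), and that of C3 with only the 2 groups compared (edgeR adjusted p = 0.0501).

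Of 35 complex I genes, 4 fell and none rose in knockout, or 24 when adjusted over the list alone (median log2 fold change -0.39, camera adjusted p = 9.52e-11, and adjusted p = 0.37 with an estimated correlation), with Ndufv3 at -0.70. No ATP synthase gene of 16 passed over all genes tested, and 13 fell when adjusted over the list alone (median -0.41, camera adjusted p = 3.28e-07, and adjusted p = 0.37 with an estimated correlation). Of 22 TCA cycle genes, 4 fell, Mdh1 (-0.89) and Idh2 (-0.88) among them, or 14 when adjusted over the list alone (camera adjusted p = 5.54e-09, and adjusted p = 0.37 with an estimated correlation). Ppargc1a had a log2 fold change of -0.63 and did not pass (edgeR adjusted p = 0.198). The Mdh1 call ended without knockout control replicates 2 or 3 or knockout IRI replicates 2 or 3 (edgeR adjusted p from 0.0574 to 0.0857). That of Idh2 ended without knockout control replicate 3 (edgeR adjusted p = 0.0534). That of Ndufv3 ended without any 1 of the wild-type control or knockout IRI libraries or knockout control replicates 2 or 3 (edgeR adjusted p from 0.0517 to 0.154). All 3 ended without the adrenal libraries (edgeR adjusted p from 0.173 to 0.373), and those of Ndufv3 and Mdh1 with the replicate block (edgeR adjusted p = 0.0922 and 0.056). Ppargc1a passed with the Y-linked covariate (-0.86, edgeR adjusted p = 0.0125). Of 29 cytosolic ribosome genes, 4 rose, or 25 when adjusted over the list alone (median 0.30, camera adjusted p = 1.95e-08, and adjusted p = 0.43 with an estimated correlation).

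Knockout IRI replicates 1 and 2 carried the adrenal transcripts, and 9 of 12 tested adrenal genes rose, or 10 when adjusted over the list alone (median log2 fold change 6.44, camera adjusted p = 1.61e-05, and adjusted p = 0.37 with an estimated correlation), Cyp11b1 (9.40) and Cyp11a1 (8.90) of steroid synthesis among them. Cyp11a1 was at 32.5, 169 and 0.124 CPM in knockout IRI replicates 1 to 3. Both calls ended without knockout control replicates 2 or 3 or knockout IRI replicate 2 (edgeR adjusted p from 0.0621 to 0.0993), with only the 2 groups compared (edgeR adjusted p = 0.0599 and 0.0581), in limma-voom (limma-voom adjusted p = 0.349 and 0.325) and without the adrenal libraries (log2 fold changes of 0.23 and -0.19). Male-biased kidney genes had a median of -2.23 with none past the threshold, also when adjusted over the list alone (camera adjusted p = 0.00241, and adjusted p = 0.43 with an estimated correlation), in libraries with 45.2, 227.4 and 1.26 CPM of Y-linked transcripts after IRI. Without the adrenal libraries, a setting chosen after seeing the data that leaves 1 knockout IRI library, 44 genes passed, all 44 among the 1215, and the adrenal list had a median of -0.44 (camera adjusted p = 0.428). With the Y-linked covariate 2226 passed, 1182 of them shared. The count was 178 without knockout control replicate 2, 213 without replicate 3, 252 and 442 without knockout IRI replicates 2 and 3, 729 and 774 without wild-type control replicates 2 and 3, and 1835 and 2889 without wild-type IRI replicates 2 and 3. DESeq2 called 2494 genes, 1209 of them shared.

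The genes called after IRI overlapped between genotypes. Of the 749 genes higher in knockout, 608 (81.2%) were also called higher in wild type, where independent lists would share 97.9, and of the 466 lower, 320 (68.7%) were called lower, where 43.8 would be shared. These comparisons share no library. Across the 19218 genes, which are not independent replicates, the log2 fold changes of the genotypes correlated with Pearson's r = 0.61 (Spearman's rho = 0.60). Among the 4607 genes called in either genotype the sign was the same for 95.1%. The median size of the log2 fold change among them, most of which were chosen by their call in wild type, was 0.88 in wild type and 0.51 in knockout, against 0.37 and 0.24 over all tested genes. With the Y-linked covariate it was 0.68 and 0.60 in the 4607 genes.

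The response to IRI was not shown to differ between genotypes for any gene. In the test of the interaction 0 of 19218 genes passed in edgeR (smallest adjusted p = 0.666), with 1350 at an unadjusted p under 0.05, while DESeq2 called 32 and limma-voom 0. The genes with the smallest p, none of which passed in edgeR, were Pla2g2c (log2 difference 3.25), Gm8982 (-2.36), Serpina1b (-3.29), Podxl2 (2.33) and Aldh1b1 (2.34), and all but Gm8982 passed in DESeq2 (DESeq2 adjusted p from 0.0069 to 0.0388). Serpina1b, an alpha-1-antitrypsin gene, had 3.24 and 34.5 CPM in wild type without and with IRI, and 25.5 and 27.7 CPM in knockout. It belongs to a family of near-identical copies whose reads may be shared. Camera's preset correlation called 18 of 42 lists, with injury genes (median -0.52), neutrophil genes (-2.44) and male-biased genes (-4.69) lower in the knockout response and adrenal genes (6.07) and segment genes of the distal tubule (0.78) higher. None of the 18 passed with an estimated correlation (the smallest camera adjusted p = 0.331). The call of the injury genes ended without knockout control replicate 1 (-0.38, camera adjusted p = 0.0591), and that of the adrenal genes without the adrenal libraries (-0.68, camera adjusted p = 0.469). With the Y-linked covariate 9 of the 18 still passed, and the call for the thick ascending limb and distal tubule ended (median 0.095, camera adjusted p = 0.304). Without knockout control replicate 1, 25 genes passed in edgeR, Serpina1b among them (edgeR adjusted p = 0.0291), and in simulated libraries the interaction test recovered 51% to 61% of the genes changed 4-fold and 7% to 8% of those changed 2-fold.

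In control kidneys few genes differed between genotypes past the threshold. Hist4h4 (ENSMUSG00000096010, chromosome 6, 136801553 to 136804415, mm10), 1 of many genes for histone H4, was at 7.20 ± 0.96 CPM in wild type and higher in knockout, at 18.8 ± 1.67 CPM (SD, n = 3), a log2 fold change of 1.38 (SE 0.12, edgeR adjusted p = 0.0035). The pseudogene Klrb1-ps1 (chromosome 6, 129116518 to 129129446) was at 0.63 CPM in wild type and 0.021 CPM in knockout, a log2 fold change of -4.79 (SE 0.51, edgeR adjusted p = 0.0125). Both have related copies elsewhere, between which the counting may have divided reads. These were the 2 genes of 19218 that passed, with 1030 at an unadjusted p under 0.05. The next by p did not pass: Ybx3, Erp27 (-2.11, edgeR adjusted p = 0.0784) and Cntn4 (-2.22, edgeR adjusted p = 0.277). The Hist4h4 call ended without wild-type control replicate 2 (edgeR adjusted p = 0.0653). That of Klrb1-ps1 ended without any 1 of the wild-type control libraries or knockout control replicates 2 or 3 (edgeR adjusted p from 0.0672 to 0.207), with the Y-linked covariate (edgeR adjusted p = 0.181) and without the adrenal libraries (edgeR adjusted p = 0.0867). Ybx3, Erp27 and Cntn4 passed in DESeq2 (DESeq2 adjusted p from 3.08e-07 to 4.27e-05). Ybx3 also passed with only the 2 groups compared (edgeR adjusted p = 0.0281) and without the intermediate libraries (edgeR adjusted p = 0.0247). Erp27 passed without wild-type IRI replicate 3 or knockout control replicate 1 (edgeR adjusted p = 0.0391 and 0.0141), and Cntn4 without wild-type IRI replicate 2 (edgeR adjusted p = 0.0204). Havcr1 (-0.19), Lcn2 (-0.45), Ppargc1a (-0.06) and Slc3a2 (-0.37), a partner of amino acid transporters and a reported target of the Ybx3 protein, had log2 fold changes within the spread (edgeR adjusted p = 0.999 each). Lcn2 turned to 0.096 without wild-type control replicate 1, and Ppargc1a to 0.075, 0.025 and 0.011 without wild-type control replicate 3 and knockout control replicates 2 and 3, and to 0.40 with the Y-linked covariate. Among 17 amino acid transport genes and reported Ybx3 targets none passed, also when adjusted over the list alone (camera adjusted p = 0.306).

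Camera called 15 lists in control kidneys, none with an estimated correlation, and no member of any list passed over all genes tested. Male-biased kidney genes had a median log2 fold change of 3.21, and 8 of 10 passed when adjusted over the list alone (camera adjusted p = 1.69e-12, and adjusted p = 0.27 with an estimated correlation). With the Y-linked covariate the median was 1.21 and the list still passed (camera adjusted p = 0.000198). Knockout control replicates 2 and 3 carried Y-linked transcripts at 248.5 and 261.2 CPM, and the wild-type control libraries did not. Female-biased genes had a median of -1.54, or -2.66 without knockout control replicate 1 (camera adjusted p = 1.57e-05, adjusted p = 0.45 with an estimated correlation, and adjusted p = 0.426 with the Y-linked covariate). Genes of the cytosolic ribosome had a median of -0.16, or -0.076 and -0.25 without wild-type control replicates 1 and 3 (camera adjusted p = 1.85e-07, and adjusted p = 0.78 with an estimated correlation), and complex I genes of -0.029 (camera adjusted p = 0.742). The count of 2 genes became 129 without knockout control replicate 1, 4 and 5 without wild-type IRI replicates 2 and 3, 0 without wild-type control replicate 2, and 1 without any of wild-type control replicates 1 and 3 and knockout control replicates 2 and 3. It was 1 with the Y-linked covariate, and DESeq2 called 72 genes. Knockout control replicate 1 had 1.18 CPM of Y-linked transcripts. For the 129 genes called without it, genotype and Y-linked level cannot be told apart.

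After IRI Hist4h4 again differed between genotypes, at 5.84 ± 0.065 CPM in wild type and 14.2 ± 0.24 CPM in knockout (SD, n = 3), a log2 fold change of 1.29 (SE 0.12, edgeR adjusted p = 0.00719). Ybx3 itself was the other of the 2 genes that passed, with 2214 at an unadjusted p under 0.05. Hist4h4 was the 1 gene called in the same direction in both conditions. With the replicate block neither gene passed (edgeR adjusted p = 0.0568 for both), nor with only the 2 groups compared (edgeR adjusted p = 0.544 and 0.711) or without the adrenal libraries (edgeR adjusted p = 0.865 and 0.915). The Hist4h4 call also ended without knockout IRI replicate 1 (edgeR adjusted p = 0.075) and without the intermediate libraries (edgeR adjusted p = 0.085). Erp27 (-2.31, edgeR adjusted p = 0.0728), Pla2g2c (2.38, edgeR adjusted p = 0.267) and Gm21742 (-2.00, edgeR adjusted p = 0.422) came next and did not pass. Havcr1 was at 616 CPM in wild type and 301 CPM in knockout (log2 fold change -1.03, SE 0.35, edgeR adjusted p = 0.422), and Lcn2 at 207 and 67.3 CPM (-1.62, SE 0.47, edgeR adjusted p = 0.422). Without wild-type IRI replicate 2 Havcr1 (-1.31), Lcn2 (-1.99), Erp27, Pla2g2c and Gm21742 passed (edgeR adjusted p from 0.0395 to 0.0486), and Erp27 also without knockout IRI replicate 3 (edgeR adjusted p = 0.0456) and with the Y-linked covariate (edgeR adjusted p = 0.0204). Erp27, Pla2g2c and Gm21742 passed in DESeq2 (DESeq2 adjusted p from 4.63e-05 to 0.0276).

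Tubular injury genes had a median log2 fold change of -0.70 in knockout against wild type after IRI, with none of 30 past the threshold over all genes and 13 lower when adjusted over the list alone (camera adjusted p = 1.12e-11, and adjusted p = 0.48 with an estimated correlation). Neutrophil genes had a median of -1.62, with 7 of 12 lower when adjusted over the list alone (camera adjusted p = 3.96e-09, and adjusted p = 0.48 with an estimated correlation), and cytokine genes of -0.53, or -0.82 and -0.24 without wild-type IRI replicates 2 and 3 (camera adjusted p = 6.5e-06, and adjusted p = 0.48 with an estimated correlation). Genes of the thick ascending limb and distal tubule had a median of 0.47, or 0.96 and 0.21 without wild-type IRI replicates 2 and 3 (camera adjusted p = 0.000106, and adjusted p = 0.67 with an estimated correlation). Adrenal genes had a median of 8.06, and 12 of 12 were higher when adjusted over the list alone (camera adjusted p = 3.75e-12, and adjusted p = 0.48 with an estimated correlation), in the group with the 271.7 and 1397 CPM of adrenal transcripts. Male-biased kidney genes had a median of -1.47 (camera adjusted p = 0.0113, adjusted p = 0.67 with an estimated correlation, and adjusted p = 0.196 with the Y-linked covariate), beside Y-linked transcripts of 206.6, 33.2 and 307.1 CPM in wild type and 45.2, 227.4 and 1.26 CPM in knockout. The male-biased call ended without wild-type IRI replicates 1 or 2 or knockout IRI replicate 3 (camera adjusted p = 0.115, 0.0652 and 0.18), and the median was -0.82 without wild-type IRI replicate 3 and -2.36 without knockout IRI replicate 2. The mitochondrial lists had medians near 0, such as 0.070 for complex I (camera adjusted p = 0.292) and 0.089 for the TCA cycle (camera adjusted p = 0.27). The count of 2 genes became 876 without wild-type IRI replicate 2, 51 without knockout IRI replicate 3, 1 without knockout IRI replicate 2, and 0 without knockout IRI replicate 1. It was 0 without both adrenal libraries, where the adrenal list had a median of 0.36 (camera adjusted p = 0.531), 0 with only these 6 libraries in the fit and 0 with the replicate block, and DESeq2 called 117 genes.

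The log2 fold changes of knockout against wild type in the 2 conditions did not go together across genes (Pearson's r = 0.062 over 19218 genes), and r was -0.064 for the 10062 genes of mean CPM of at least 10. Male-biased kidney genes had a positive median in control kidneys and a negative one after IRI. Adrenal transcripts were high only in libraries of the knockout IRI group. For these reasons r does not isolate the effect of the deletion. Genes called between genotypes lay near Ybx3. Both called genes other than Ybx3, Hist4h4 at 5.41 Mb and Klrb1-ps1 at 2.24 Mb, were among the 377 tested genes within 20 Mb, and none was among the 18834 elsewhere (Fisher's exact test, two-sided, p = 0.000384). In the mean of the genotype comparisons, a contrast chosen after seeing the data, 5 genes passed, all on chromosome 6: Hist4h4 (edgeR adjusted p = 0.000139), Ybx3 (edgeR adjusted p = 0.000916), Erp27 (edgeR adjusted p = 0.00274), Klrb1-ps1 (edgeR adjusted p = 0.0034) and Cntn4 (edgeR adjusted p = 0.0365). At an unadjusted p under 0.001 in this contrast, 11 of the 377 genes within 20 Mb of Ybx3 (2.92%) and 25 of the 18834 elsewhere (0.133%) were found, Ybx3 left out (Fisher's exact test, two-sided, p = 5.57e-11). Fisher's test takes genes as independent, but some of these are close neighbours. Hist4h4, Mgp, Erp27 and Pde6h lay 5.41 to 5.54 Mb from Ybx3, so that the p does not count separate events.

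**Figure D3:**
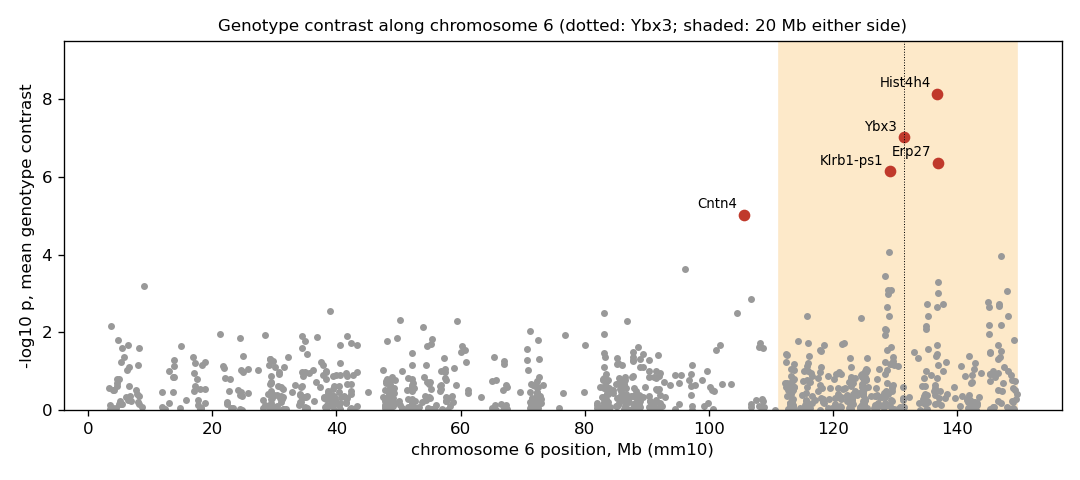
The -log10 of the unadjusted edgeR p (vertical axis) of each tested gene on chromosome 6 in the mean of both genotype comparisons, by position in Mb of mm10 (horizontal axis); the dotted line marks Ybx3, the shaded area 20 Mb on either side, and red points the 5 genes past the adjusted threshold. Of these, 4 lie in the shaded area and Cntn4 lies 24.7 Mb from Ybx3.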

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

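The tests on adrenal transcripts and on the Y-linked covariate, and the fits without the intermediate or adrenal libraries, were chosen only after data were seen. For the fit without the intermediate libraries the prediction was written before its own result. Fisher's exact test of called genes near Ybx3 was planned, but its prediction and the other tests on these genes were written after results were seen. Leaving out wild-type IRI replicate 3 and the other splits of the libraries were planned, with predictions written before. How 6 of the values are read was altered after they were seen: by the rules set first, 1.02 spoke against a switch-on of steroid synthesis, 0.472 for male RNA, 1.18 for the distance of wild-type IRI replicate 3, 3.70 against adrenal and mixed RNA, 0.000384 for flanking sequence, and 60 of 60 for chance in the interaction. All 6 values are now read as open, for the reasons given below. Adrenal medulla genes argue against the switch-on.

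The responses to IRI differed between genotypes for 18 gene lists by camera's test of the interaction at a preset correlation, and for none with an estimated correlation (camera adjusted p from 0.331 upwards) or by fry (limma, adjusted p from 0.374 upwards). The median log2 differences, knockout response minus wild-type response, were -0.52 for tubular injury and repair, -2.44 for neutrophil genes, -0.48 for cytokines, -0.66 for the cell cycle, -0.42 for p53 and cell cycle arrest, -0.24 for antioxidant defence and -0.57 for immediate early genes. They were 0.78 for the thick ascending limb and distal tubule, 0.72 for the collecting duct, 0.63 for podocytes, 0.44 for extracellular matrix, 0.27 for interferon response and 0.26 for complement and antigen presentation. Lists of other tissues and of sex had -2.37 for erythrocytes, 6.07 for the adrenal gland, 1.20 for adipose tissue, -4.69 for male-biased and 2.16 for female-biased kidney genes. With the Y-linked covariate 9 of the 18 still passed, and 6 no longer did: thick ascending limb and distal tubule (0.095), collecting duct (0.055), podocyte (0.054), p53 and cell cycle arrest (-0.30), antioxidant defence (-0.096) and female-biased kidney genes (0.55). The other 3, extracellular matrix (-0.018), cytokines (0.047) and immediate early genes (-0.050), changed direction in camera and did not pass. Leaving out 1 library ended the calls of tubular injury (-0.38 without knockout control replicate 1), extracellular matrix (0.26 without wild-type IRI replicate 3), cytokines (-0.065, -0.27 and -0.29 without wild-type IRI replicate 3, knockout control replicate 1 and knockout IRI replicate 1), interferon response (0.17 and 0.26 without wild-type IRI replicates 1 and 2), cell cycle (-0.65 without wild-type IRI replicate 2) and p53 (-0.47 without knockout control replicate 1). It also ended those of immediate early genes (-0.45, 0.012, -0.47 and -0.37 without wild-type control replicate 2, wild-type IRI replicate 3, knockout control replicate 1 and knockout IRI replicate 1) and adipose tissue (0.39, 1.02 and 0.74 without wild-type control replicate 1, wild-type IRI replicate 2 and knockout control replicate 2). Medians that moved by over 1.5 times and still passed were, without wild-type IRI replicate 3, 0.38 for podocytes, 0.47 for interferon response, -0.26 for p53 and -1.41 for erythrocytes, and without wild-type IRI replicate 2, -0.72 for cytokines, -0.86 for immediate early genes and 3.61 for female-biased genes. Without knockout control replicate 1 they were -0.41 for antioxidant defence, 2.35 for adipose tissue and 3.64 for female-biased genes, without replicate 2, -0.26 for cytokines and 0.41 for interferon response, and without replicate 3, -0.32 for the cell cycle. Without wild-type control replicate 1 they were -0.36 for antioxidant defence and -0.90 for immediate early genes, without wild-type IRI replicate 1, -0.38 for antioxidant defence, and 0.18 and 0.16 for complement without wild-type control replicate 2 and knockout IRI replicate 3.

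Adrenal transcripts stood at 271.7 and 1397 CPM in knockout IRI replicates 1 and 2. A switch-on of steroid synthesis in injured knockout kidney is argued against by 5 genes of the adrenal medulla, which makes no steroids. Chgb had 13.7, 65.0 and 0.173 CPM in replicates 1 to 3 and Th 3.77, 22.9 and 0.0247 CPM. Replicate 3, at 1.02 times the wild-type IRI mean, decides nothing: it is 1 library and the lowest in Havcr1 (204.4 CPM, with 234.4 in replicate 1). Separate pieces of adrenal gland in each sample give no reason for the Y-linked and adrenal excess of replicate 1 to be the same share of replicate 2, and the ratio of these shares was 1.01. RNA or reads of replicate 2 in replicate 1 stay open. The share was 0.194 from Y-linked genes and 0.164 to 0.237 for 15 adrenal genes. The origin of the adrenal RNA of replicate 2 was not tested. All tests and SDs with knockout IRI take its libraries as independent, which mixing would break.

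More genes were called after IRI in wild type (4320) than in knockout (1215), a ratio of 3.56, while the interaction called 0 genes in edgeR (1350 at an unadjusted p under 0.05, DESeq2 32, limma-voom 0). An unequal share of male RNA stays open. At equal residual spread the Y-linked covariate widens standard errors 1.2-fold in wild type and 1.04-fold in knockout. With it the ratio was 0.472 and median log2 fold sizes 0.682 and 0.601. But every wild-type IRI library held at least 10.8% of the highest Y-linked level and every wild-type control at most 0.583%, unlike in knockout. The 3 IRI libraries highest in it were also highest in Havcr1. The covariate takes up part of the wild-type response whatever its cause and does not separate male RNA from degree of injury. Without wild-type IRI replicate 3 the ratio was 1.18, but the knockout count moved more (to 2889) than the wild-type count (to 3410) and the median sizes were 0.745 and 0.506, against 0.884 and 0.506 with it, which leaves that library's part open. Adrenal and mixed RNA in the knockout group also stays open: the ratio was 3.70 without the intermediate libraries, a setting that keeps knockout IRI replicate 2 and drops wild-type IRI replicate 2 (7129 genes in wild type without it alone), so that the bound of 1.5 set for it was wrong, and it was 15.8 without knockout IRI replicate 2 and 67.4 without both adrenal libraries, with fewer libraries in that group; a difference between the genotypes stays open too.

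Genes called for genotype lay near Ybx3. A share of male RNA as the cause is argued against, since with the Y-linked covariate the genes at p under 0.001 were still concentrated within 20 Mb (Fisher's exact test, two-sided, p = 4.66e-11). The concentration of called genes itself (Fisher's exact test, two-sided, p = 0.000384) is the pattern and favours no local cause over another. Both tests take neighbouring genes as independent. Flanking sequence of the strain in which the deletion was made, and an effect of the deletion on its neighbours or of the protein on these genes, cannot be told apart, since no strain sequence was analysed here and the 11 genes at p under 0.001 went both ways, 63.6% higher in knockout.

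Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. IRI in wild type called 4320 genes and the highest other split 0, counting 1 split as large. IRI in knockout called 1215 and the highest other 1, again 1 split as large. Knockout in control kidneys called 2 and the highest other 1, again 1 split as large. Knockout after IRI called 2, and 2 splits were as large, the highest other calling 1178. That split set wild-type IRI replicates 1 and 3 and knockout IRI replicate 2 against the rest, and points to a structure of the samples. These 3 were the IRI libraries highest in Y-linked transcripts, in Havcr1 (768.8, 720 and 463.1 CPM against 358.2, 234.4 and 204.4) and on the first principal component (67.0, 111.8 and 48.3 against 13.3, 4.27 and 15.9), so that the split follows sex-linked signal and degree of injury alike. For the interaction the real labelling called 0 genes, so that all 60 labellings drawn of 200, the real one included, called at least as many whatever the data, and the count decides nothing. The highest other called 559, which points to a structure of the samples as well.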

How the results depend on the processing

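The Y-linked covariate, the fits without adrenal or intermediate libraries or without small RNA and pseudogenes, and the mean genotype contrast were chosen only after the results were seen. Causes of the changes given here were not tested. Of 1921 results of single genes under alternatives set in advance, 1747 kept their direction and side of the threshold, 159 no longer passed, 11 newly passed and 4 reversed. Under added ones the numbers were 704, 150, 5 and 10 of 869, and leaving out a library 2104, 476, 17 and 19 of 2616. For lists, 711 of 926 kept both and 215 no longer passed under alternatives set in advance, 342 of 380 under added ones and 1085 of 1140 without a library. The alternatives set in advance include scaling without mitochondrial and ribosomal RNA genes. It could change little, since the mitochondrial genes were at 0 in every library, and all its results stayed the same. Replicate numbers did not pair the libraries: the correlation of same-numbered deviations ran from -0.417 to 0.077, and 0 of 12 libraries correlated best with their own number. Library sizes without TMM moved the median of all genes by 0.11 in knockout against wild type after IRI and by 0.14 in the interaction.

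Genes called for IRI in wild type (4320) numbered 1928 at a log2 fold of at least 1, 1232 with only the groups compared, 2730 with the replicate block, 1050 with the Y-linked covariate, 6549 without the intermediate libraries, and 1570 (without wild-type control replicate 2) to 7129 (without wild-type IRI replicate 2) leaving out a library. For IRI in knockout (1215) they numbered 678 at a log2 fold of at least 1, 2494 with DESeq2, 469 with the block, 2226 with the covariate, 44 without the adrenal libraries, and 178 (without knockout control replicate 2) to 2889 (without wild-type IRI replicate 3). For knockout in control kidneys (2) they numbered 72 with DESeq2, 5 with only the groups compared, 1 each at a CPM of at least 1 in 3 samples, with the covariate, without the adrenal libraries and without small RNA and pseudogenes, and 0 to 129 leaving out a library. For knockout after IRI (2) they numbered 117 with DESeq2, 0 each with only the groups compared, the block and without the adrenal libraries, 1 without the intermediate libraries, and 0 to 876. The interaction (0 in edgeR, 1350 at an unadjusted p under 0.05) had 32 with DESeq2, 0 with limma-voom and 0 to 25 leaving out a library.

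Ybx3 in control kidneys newly passed with DESeq2 (log2 fold change -1.65), only the groups compared (-1.65) and without the intermediate libraries (-1.65), and ran from -1.83 to -1.58 leaving out a library. After IRI Ybx3 no longer passed with only the groups compared (-2.33), the block (-2.30) and without the adrenal libraries (-2.10), and ran from -2.54 to -2.09. Genes called in both genotype comparisons (1) numbered 6 with DESeq2, 0 with the block or without the adrenal libraries, and 0 to 3. Called genes near Ybx3 (2) numbered 11 at p under 0.001 in the mean contrast. List calls were 0 in each of the 5 comparisons with an estimated correlation. With fry they were 22 (directional) and 35 (mixed) for IRI in wild type, and 16 and 28 for IRI in knockout. They were 0 (directional) in both genotype comparisons and the interaction, and 1, 1 and 0 (mixed). Leaving out a library they were 22 to 25 for IRI in wild type, 21 to 25 for IRI in knockout, 14 to 21 and 14 to 22 for knockout in control and IRI kidneys, and 15 to 21 for the interaction. The correlation of IRI fold changes (0.612) was 0.755 among called genes and 0.648 at a mean CPM of at least 10, and that of the genotype fold changes reversed to -0.064.

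Single genes reversed as follows, by log2 fold change. Slc3a2 for IRI in wild type had -0.018 without wild-type control replicate 3, -0.16 without wild-type IRI replicate 3 and -0.094 with the covariate, reaching 0.28 without wild-type IRI replicate 2. For IRI in knockout Slc3a2 had -0.055 without knockout IRI replicate 2, up to 0.16 without knockout control replicate 1, and -0.025 without the adrenal libraries. Cyp11a1 for IRI in knockout had -0.19 without the adrenal libraries. In control kidneys Ybx2 had 0.34 with the covariate, Lcn2 0.096 without wild-type control replicate 1 (lowest -0.82 without wild-type control replicate 2), and Ppargc1a 0.075 without wild-type control replicate 3, 0.025 and 0.011 without knockout control replicates 2 and 3 (lowest -0.22 without replicate 1), and 0.40 with the covariate. After IRI Umod had -0.091, -0.10 and -0.047 without wild-type IRI replicates 1 and 3 and knockout IRI replicate 3 (highest 0.40 without wild-type IRI replicate 2), and -0.10 with the covariate. In the interaction Havcr1 had 0.20 and Ppargc1a -0.084 with the covariate. Slc3a2 had 0.12 without TMM, 0.22 with the covariate, and 0.085, 0.23, 0.059 and 0.029 without wild-type control 3, wild-type IRI 3, knockout control 1 and knockout IRI 1, with a lowest value of -0.21 without wild-type IRI 2. Krt18 had 0.094 without TMM, 0.0057 with limma-voom, 0.016 with the replicate block and 0.011 with the covariate. Krt18 also had 0.060, 0.034, 0.064, 0.32 and 0.15 without wild-type control 2, wild-type IRI 1, wild-type IRI 3, knockout control 1 and knockout IRI 1, and its lowest value was -0.33 without knockout IRI 2.

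Lists reversed by camera's direction, with the following medians. With the covariate in control kidneys the thick ascending limb and distal tubule list had 0.13 and podocyte 0.052, while fibroblast and extracellular matrix at -0.0041 and collecting duct at -0.043 kept the sign of the median. Cell cycle in control kidneys had -0.21 without knockout control replicate 3 and up to 0.53 without replicate 1. The adrenal gland list had -0.44 for IRI in knockout and -0.68 in the interaction without the adrenal libraries. In the interaction with the covariate, fibroblast and extracellular matrix had -0.018, cytokines and NF-kB response 0.047 and immediate early genes -0.050, a median of unturned sign. Immediate early genes had 0.012 without wild-type IRI replicate 3 and down to -0.90 without wild-type control replicate 1.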

Other observations

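All tests of annotation terms given here were chosen after the data were seen. Among genes higher after IRI in wild type, those of protein synthesis and breakdown were frequent. Of 85 tested genes of ribosome biogenesis 47 were called higher where 11.8 were expected (hypergeometric test, one-sided, Benjamini-Hochberg adjusted p over 3256 terms = 8.13e-16). Of 62 genes of the proteasome 33 were called higher where 8.58 were expected (hypergeometric test, adjusted p = 1.96e-10), and of 12 genes of the aminoacyl-tRNA synthetase complex 9 where 1.66 were expected (hypergeometric test, adjusted p = 0.000419). Among genes lower in wild type, 20 of 69 of the brush border membrane were called where 6.94 were expected (hypergeometric test, adjusted p = 0.0018). In knockout 10 of the 69 were called lower where 1.80 were expected (hypergeometric test, adjusted p = 0.00362).

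Among genes higher after IRI in knockout, 9 of 29 of the acute-phase response were called where 1.25 were expected (hypergeometric test, adjusted p = 0.00107) and 11 of 58 of blood coagulation where 2.51 were expected (hypergeometric test, adjusted p = 0.00526). In wild type 15 of these 58 were called lower where 5.84 were expected (hypergeometric test, adjusted p = 0.0401). These need not be the genes called higher in knockout, and the number called higher in wild type is not reported here. Among genes lower in knockout, 15 of 64 of flavin adenine dinucleotide binding were called where 1.67 were expected (hypergeometric test, adjusted p = 1.08e-07; 18 in wild type where 6.44 were expected, adjusted p = 0.00589) and 8 of 27 of sterol biosynthesis where 0.703 were expected (hypergeometric test, adjusted p = 0.000232). These terms were not tested for a difference between genotypes.

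Rn7s1 and Rn7s2, copies of the signal recognition particle RNA gene, had nearly equal counts in every library, with Rn7s1 at 99.973% to 99.991% of Rn7s2. Protein-coding genes held 74.8% to 79.7% of the counts.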
